A study of Mus musculus with 2 samples.

How the data were processed

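Whole testes of 1 WT and 1 RAD21L KO mouse, aged 55 days per the labels, were profiled by droplet-based single-cell RNA sequencing on a NovaSeq 6000 per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode. They were made with Cell Ranger 6.1.2 per the file headers and the submitters' processing notes, which also name Seurat 4.3 and the GRCm39 genome build. How barcodes were called as cells is not stated. Each matrix lists 41459 genes by symbol. The sorted cells and chromosome contact data that the series describes were not used here.

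Barcodes were kept with at least 500 detected genes and at most 20% mitochondrial UMIs, counted over 24 mitochondrial genes (ribosomal and transfer RNAs). Mitochondrial mRNAs were not in this count. In WT, 8 barcodes had fewer genes and 7 had more mitochondrial UMIs; in KO, 709 and 30. Doublets were called in each library with Scrublet as built into Scanpy 1.11.5, with an expected rate of 5%. In WT it marked 1 of 5400 cells (0.0185%), below the 0.5% set as the least for a working call, so it had not worked and no WT cell was removed. In KO it marked 126 of 6381 cells (1.97%), which were removed, so doublets were treated unequally. This left 5400 WT and 6255 KO cells.

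Both libraries were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen per library, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1 gave 28 clusters, without integration. Shared-neighbour edges under 1/15 were dropped. Clusters were named from fixed markers of 14 classes (260 of 261 marker genes were found), and the names carry "-like" since they rest on markers alone. A name needed at least 3 detected markers. A class whose markers led the 10 leading genes came first, then the highest marker score. Clusters with a tie, with leading genes of another class, or with median UMIs under 1/3 of their library's median were left unnamed. Undifferentiated and differentiating spermatogonia were joined as 1 class.

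UMIs were summed per library and class and scaled to CPM. The 2 classes with at least 50 cells in both libraries were compared. The libraries summed to 33096309 UMIs in WT and 28001992 in KO. Levels have exact Poisson 95% intervals, shares exact Clopper-Pearson intervals and ratios of UMIs exact conditional binomial intervals. Ratios of cell numbers have 95% intervals from Poisson draws, in which a drawn WT somatic-like count of 0 was set to 1. All of these cover counting error only. A share of 0 is given with the limit of 3 counts of the total. With 1 library per genotype no test, p-value or count of changed genes was computed, since cells are not replicates of a genotype.

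A gene was named if it had at least 50 UMIs in the library where it was higher and if that CPM, less 10% of the gene's CPM over all kept cells of the same library as room for free RNA, was still at least 2 times the other, with counts of under 3 set to 3. That floor holds for the ranks and for medians, while ratios of single genes are printed as counted, with their interval. Predicted genes, mitochondrial genes, ribosomal proteins, haemoglobins and Rad21l were left out. The first 12 in each direction per germ cell class are named. Always named were Rad21l, Rec8, Smc1b, Stag3, Rad21, Zfy1 and Zfy2, and members of the fixed lists with the largest ratios. Genes named from the sub-clusters and from clustering without sex-linked genes include some chosen after their values were seen.

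Medians of 18 fixed lists (338 of 345 members found) were taken over members with at least 20 UMIs in both libraries together, for lists with at least 3 such members. Their percentile is among 10000 random lists of the same size matched on mean CPM in 20 bins, and describes these libraries only. Intervals of medians came from 500 Poisson draws. X-linked (1526) and Y-linked (295) genes were assigned by symbol from a GRCm38 annotation, of which no coordinates were used; 1493 genes with 2.79% of UMIs had no chromosome. The X-linked result is the median log2 ratio of X-linked genes minus that of autosomal genes, with counts under 3 set to 3.

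The filters, markers, lists, naming rule for genes and 29 alternatives were chosen before the data were examined. Chosen after were the form of the neighbour graph, the order of the cluster naming rule and its limit on UMIs, the exclusion of LOC symbols from named genes, the setting of low counts to 3 in list and X-linked medians, the sub-clusters and 11 further alternatives. For the sub-clusters, spermatogonia-like and spermatocyte-like cells of each library were clustered again and early prophase-like sub-clusters were grouped by whether Stra8 or Rad51ap2 was among their leading genes.

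The steps were tested on simulated data with 100 genes set to a 4-fold and 100 to an 8-fold difference. These were drawn only from autosomal genes with enough expected UMIs and a level above the room for free RNA. Sums were Poisson draws with no free RNA and no difference in stage added, so recovery in the real data can be lower. In both classes 100% of each were recovered, and of 21948 unchanged genes 35 in spermatogonia-like and 28 in early prophase-like cells were named. An X-linked shift set at 1 was found as 0.97 and 0.93, and a list shift set at 2 as 2.02 and 2.06. Other software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9.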

Results

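Single-cell RNA sequencing by droplet capture counted unique molecular identifiers (UMIs, each standing for 1 captured transcript) in whole testes of mice aged 55 days. There was 1 library from a wild-type (WT) mouse and 1 from a mouse lacking RAD21L (RAD21L KO), a cohesin subunit of meiosis. The WT library held 5415 barcodes and 33096309 UMIs, and the KO library 7118 barcodes and 28001992 UMIs, against a target of 5000 to 6000 cells each. After filtering, 5400 WT cells with a median of 2230.5 UMIs and 6255 KO cells with a median of 3429 UMIs were kept. With 1 library per genotype there were no replicates and no test was run, so each difference is one between these libraries. Ranges in parentheses are 95% intervals that cover counting error only, except where they are given as ranges of random lists. They are exact for levels (Poisson), shares (Clopper-Pearson) and ratios of UMIs (conditional binomial). Those of medians and of ratios of cell numbers came from Poisson draws.

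The first comparison asked whether the targeted gene differed between the libraries. In early meiotic prophase-like cells, Rad21l stood at 89.0 CPM (UMIs of the gene scaled to a common total) in WT (64.4 to 120, 43 UMIs) and 22.4 CPM in KO (16.9 to 29.2, 55 UMIs). The WT level was 3.97 times the KO level (2.60 to 6.03). Under a looser cell filter, which left 0 WT spermatogonia-like cells, the early prophase-like class stood at 37.0 CPM in WT and 22.1 CPM in KO. In spermatogonia-like cells it was 14.5 CPM in WT (8.26 to 23.5, 16 UMIs) and 7.62 CPM in KO (5.49 to 10.3, 42 UMIs), and the ratio of 1.90 had an interval that included 1 (0.996 to 3.45). A Rad21l UMI was found in 31.1% of WT and 9.58% of KO early prophase-like cells, at median depths of 5035.5 and 4121 UMIs. For background, 0.265% of KO Sertoli-like cells (median 6946 UMIs) had one, a level of 0.351 CPM. Over all barcodes, Rad21l was at 2.48 CPM in WT (1.97 to 3.08) and 3.96 CPM in KO (3.26 to 4.77). The labels do not state which part of the gene the allele lacks, so UMIs that remain in the KO library check the genotype only in part.

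**Figure D1:**
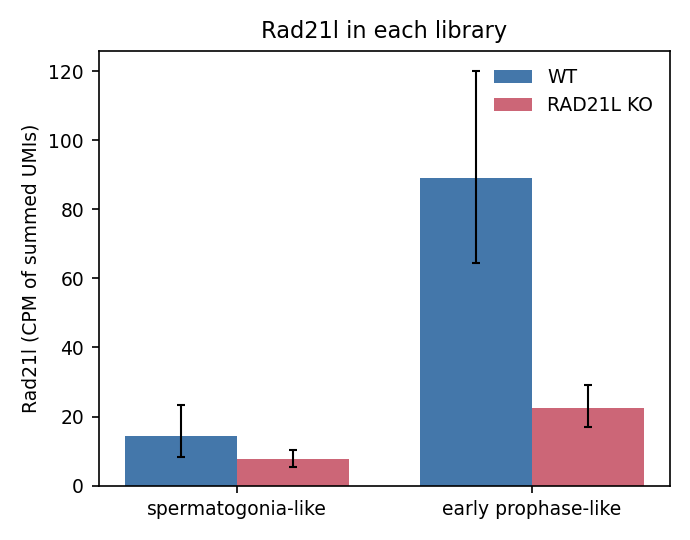
Rad21l in CPM of summed UMIs (vertical axis) in spermatogonia-like and early prophase-like cells of the WT and RAD21L KO libraries; bars are single libraries and error bars are exact 95% Poisson intervals. In early prophase-like cells the WT bar stands at 89.0 CPM and the KO bar at 22.4 CPM.

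The second comparison asked how far germ cells had advanced in each testis. The WT library was mostly made of spermatids and pachytene-like spermatocytes, and no KO cell fell in a cluster with those names. KO germ cells were spermatogonia-like or early prophase-like, and somatic-like cells made up much of the rest. Pachytene-like and later cells were 83.2% of WT cells (4493 of 5400; 82.2% to 84.2%) and 0 of 6255 KO cells, which allows a share of up to 0.0480% (3 counts of the total). When KO cells were instead projected onto WT clusters, 1.34% of them fell in these classes. Of the WT cells, 17.3% were pachytene and diplotene-like, 42.3% round spermatid-like and 23.7% elongating spermatid-like. Spermatogonia-like cells were 3.11% of WT cells (2.66% to 3.61%) and 15.2% of KO cells (14.3% to 16.1%). Early prophase-like cells were 1.67% of WT cells (1.34% to 2.04%) and 8.35% of KO cells (7.67% to 9.06%). The split of WT cells between these classes depended on the settings: spermatogonia-like cells were 0% to 4.94% of WT cells and early prophase-like cells 0.312% to 4.87%, and the KO share of each was the larger in every setting. Among germ cells alone, spermatogonia-like cells were 3.54% in WT and 64.5% in KO, and early prophase-like cells 1.89% and 35.5%.

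Somatic-like cells were 1.17% of WT cells (63 cells) and 49.5% of KO cells (3095 cells). Sertoli-like cells were 0.685% of WT and 18.1% of KO cells, and Leydig-like cells 0.130% (7 cells) and 11.7% (729 cells). The Sertoli-like share depended on how clusters were made and named: in WT it was 5.35% under the strict filter and 11.5% without sex-linked genes in clustering, and in KO 33.7% with low-UMI clusters named. The somatic-like totals depend on it too. Stromal-like cells were 0.111% and 10.9%, myeloid-like cells 0.130% and 6.11%, myoid-like cells 0.0926% and 1.57%, and endothelial-like cells 0.0185% and 1.17%. Among somatic-like cells alone, Sertoli-like cells were 58.7% in WT (45.6% to 71.0%) and 36.5% in KO (34.8% to 38.3%). No cluster was named lymphocyte-like or erythroid-like. Clusters left unnamed held 10.9% of WT and 27.0% of KO cells. In WT, 583 of the 586 unnamed cells sat in a cluster led by Defb45, Serpina3a and Cst9 together with spermatid genes. In KO, clusters of 974, 453, 144, 60 and 34 cells were left unnamed for their few UMIs per cell, and another of 23 cells for its mixed leading genes.

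The germ cell classes of the libraries sat in different clusters, and a cluster made almost wholly of 1 library may reflect that library rather than a cell type. Spermatogonia-like cells came from cluster 18 in WT (167 cells) and cluster 2 in KO (950 cells). Early prophase-like cells came from cluster 22 in WT (89 cells) and in KO from cluster 14 (304 cells, led by Meiosin and Prdm9) and cluster 17 (218 cells, led by Dcaf8l, Ccnb3 and Rad51ap2).

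**Figure D2:**
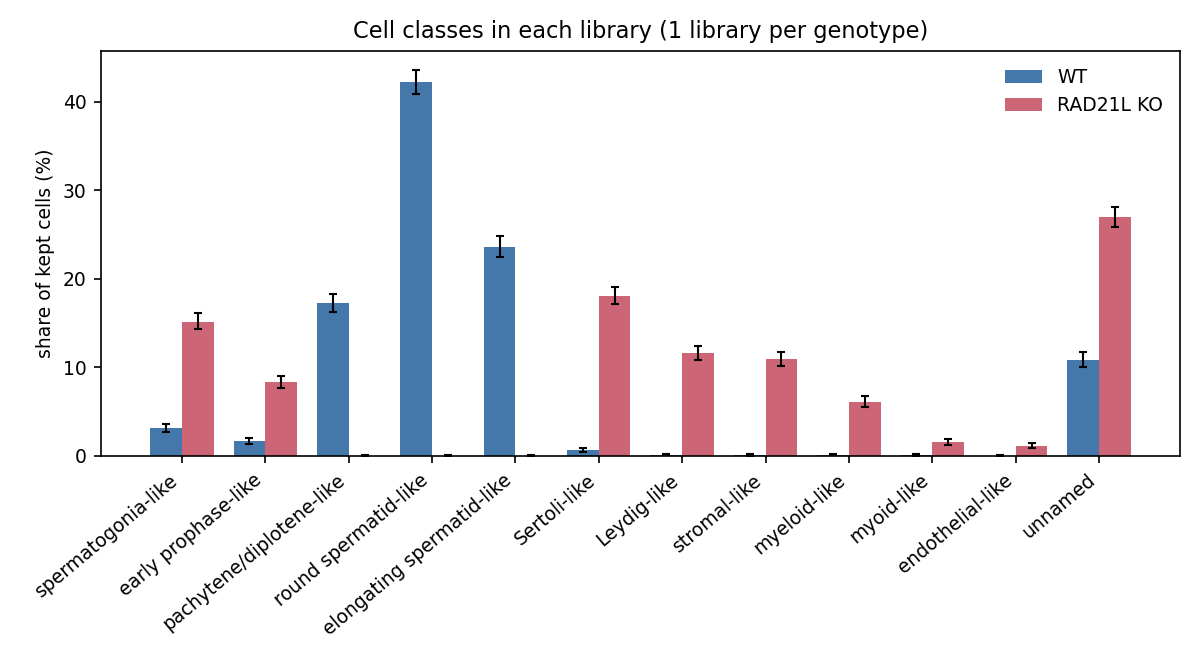
Share of kept cells (vertical axis, percent) in each class for the WT and RAD21L KO libraries; bars are single libraries and error bars are exact 95% Clopper-Pearson intervals. Spermatogonia-like cells are 3.11% in WT and 15.2% in KO, and the classes from pachytene-like onward hold 0 KO cells.

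Marker transcripts were also counted over all barcodes, with no clustering. The markers of spermatids and pachytene spermatocytes again stood far lower in KO, while those of early prophase took like shares in both libraries. The markers of elongating spermatids took 7.80% of WT UMIs and 0.0171% of KO UMIs, and those of round spermatids 0.489% and 0.00297%. The markers of pachytene and diplotene spermatocytes took 1.67% and 0.0534%, while those of early prophase took 0.317% and 0.309%. The markers of undifferentiated spermatogonia took 0.0174% in WT and 0.118% in KO, and those of differentiating spermatogonia 0.0613% and 0.103%. Single genes weighed on both sets. Without Sdc4, at 18.8 CPM in WT and 489 CPM in KO, the first pair was 0.0155% and 0.0695%. Without Dmrtb1, which went the other way at 459 and 17.0 CPM and gave 74.9% of the WT UMIs of its set, the second was 0.0154% and 0.101%. The markers of Sertoli cells took 0.0940% and 1.54%, and those of Leydig cells 0.0142% and 0.811%. Among single genes, chosen after their values were seen, Prm2 stood at 19041 CPM in WT and 0.750 CPM in KO, Piwil1 at 503.6 and 4.50 CPM and Zbtb16 at 7.95 and 75.3 CPM. Early prophase markers went either way, with Dmc1 at 9.79 and 41.0 CPM and Spo11 at 42.1 and 7.79 CPM. The like share of that set is a sum of markers that differed, and does not show like numbers of early prophase cells.

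Free RNA differed between the preparations and bears on every germ cell comparison. In WT, elongating spermatid markers took 1.52% of UMIs in somatic-like cells, 1.48% in spermatogonia-like cells and 1.52% in early prophase-like cells. In KO, Sertoli markers took 0.258% of UMIs in spermatogonia-like and 0.321% in early prophase-like cells, which is 16.8% and 20.9% of their level in the whole KO library. The WT values of the same Sertoli markers were 0.0387% and 0.0586%. Spermatid genes higher in WT germ cells and Sertoli or Leydig genes higher in KO germ cells were therefore read as background.

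The next comparison asked whether X-linked and Y-linked genes differed between the libraries in early prophase-like cells, since the sex chromosomes are normally silenced as spermatocytes reach pachytene. X-linked genes stood higher than autosomal genes in the KO library, and Y-linked genes did too. The difference was larger in cells of sub-clusters led by Rad51ap2 than in those led by Stra8. X-linked genes took 1.57% of UMIs in WT (1.54% to 1.61%) and 3.12% in KO (3.09% to 3.14%), and Y-linked genes 0.0766% and 0.185%. Over 423 X-linked genes, the median log2 ratio of KO over WT exceeded that of 10090 autosomal genes by 0.91 (0.84 to 0.96), and 392 of the 423 lay above the autosomal median. The median of the X-linked genes was 1.09, at percentile 100 of 10000 random lists of autosomal genes matched on level, whose central range was 0.20 to 0.32. With 20% of each library's own profile taken off as free RNA, an alternative chosen after the data were seen, the difference was 0.65 (0.59 to 0.72).

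After clustering the germ cells of each library again, the Stra8-led cells had X-linked shares of 2.55% in WT (52 cells) and 3.28% in KO (216 cells), and a median difference of 0.35 (0.26 to 0.40). No free RNA was taken off in the sub-clusters. All kept cells together held 0.906% X-linked UMIs in WT and 3.56% in KO, so free RNA acts in the direction of the Stra8-led difference. How much of that difference is free RNA was not tested. The Rad51ap2-led cells had shares of 0.836% in WT (51 cells) and 3.01% in KO (202 cells), and a median difference of 1.57 (1.47 to 1.64). The Y-linked shares were 0.124% and 0.181% in Stra8-led cells, and 0.0495% and 0.186% in Rad51ap2-led cells. In WT pachytene and diplotene-like cells, X-linked genes took 0.135% of UMIs. The sub-clusters were matched by their leading genes and not by stage, and Piwil1 stood at 498.3 CPM in the WT and 40.4 CPM in the KO Rad51ap2-led cells. They were made with sex-linked genes kept, so their X-linked and Y-linked shares can depend in part on the grouping. Clustering without sex-linked genes was run for the whole class and not for the sub-clusters.

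**Figure D3:**
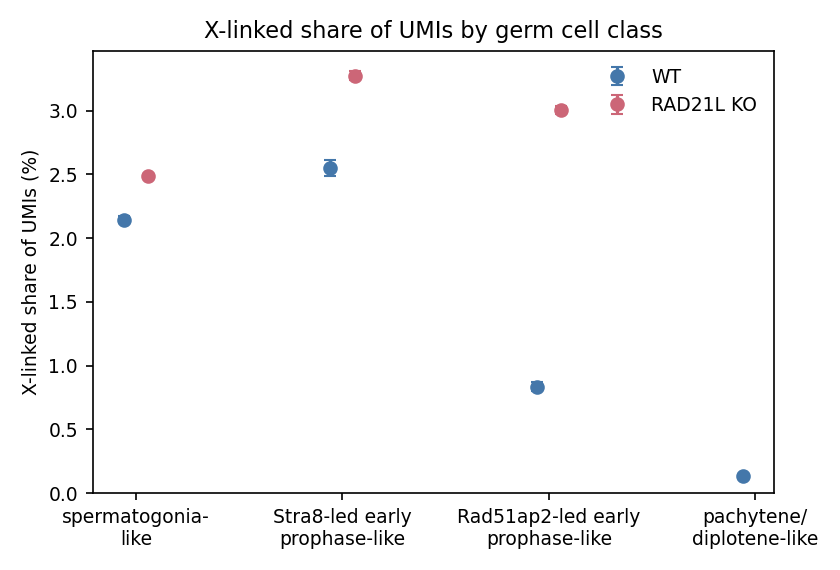
Share of UMIs from X-linked genes (vertical axis, percent) in germ cell classes and sub-clusters of the WT and RAD21L KO libraries; points are single libraries and error bars are exact 95% Clopper-Pearson intervals. In Rad51ap2-led cells the WT share is 0.836% and the KO share 3.01%.

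Zfy1 and Zfy2, both Y-linked, stood at 26.9 and 14.5 CPM in WT early prophase-like cells and at 168 and 145 CPM in KO (log2 2.64, 1.85 to 3.56, and 3.32, 2.26 to 4.64). Since both genes led KO cluster 17, cells were also clustered without X-linked and Y-linked genes, which gave 26.0 and 167 CPM for Zfy1 and 8.01 and 145 CPM for Zfy2. In that clustering Usp9y stood at 54.1 CPM in WT and 206 CPM in KO, Scml2 at 244.3 and 839 CPM, Ccnb3 at 82.1 and 321 CPM, and Nxt2 at 10.0 and 91.7 CPM. In Stra8-led cells Zfy1 was at 24.4 CPM in WT and 30.2 CPM in KO, and Zfy2 had 0 UMIs in WT and stood at 10.4 CPM in KO, so no difference was detectable at this depth. In Rad51ap2-led cells Zfy1 was at 26.6 and 332 CPM and Zfy2 at 13.3 and 299 CPM. Ccnb3 was at 106 CPM in WT and 83.4 CPM in KO in Stra8-led cells, and at 56.5 and 488.5 CPM in Rad51ap2-led cells. Usp9y and Ccnb3 were also among the leading genes of KO cluster 17. The sub-clusters were made with sex-linked genes kept. The levels of these genes in Rad51ap2-led cells can therefore follow in part from how the cells were grouped.

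**Figure D4:**
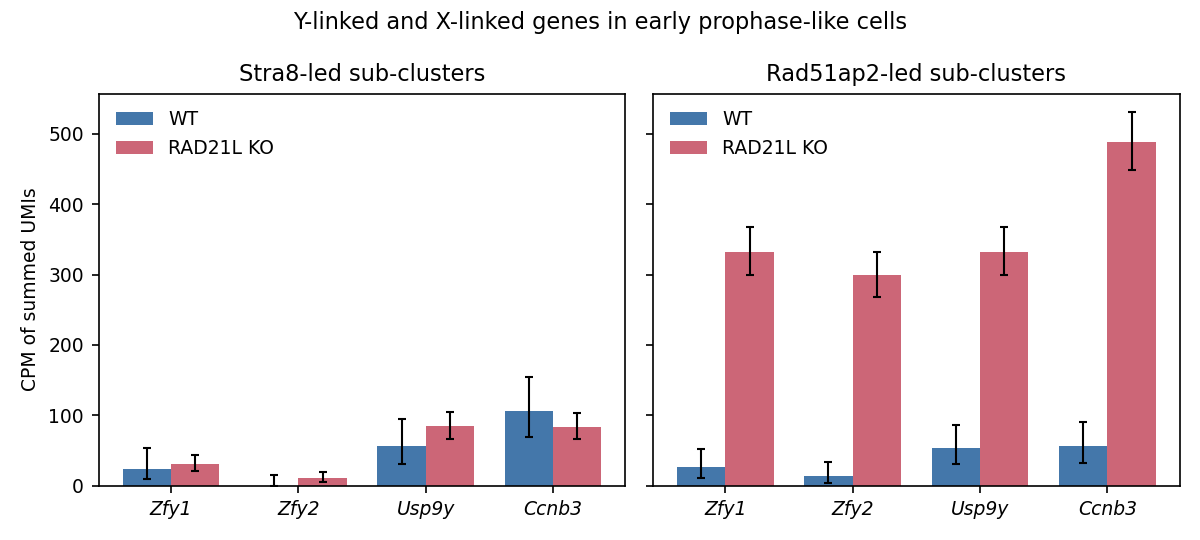
CPM of summed UMIs (vertical axis) of Zfy1, Zfy2, Usp9y and Ccnb3 in Stra8-led and Rad51ap2-led early prophase-like cells of the WT and RAD21L KO libraries; bars are single libraries and error bars are exact 95% Poisson intervals. In Rad51ap2-led cells Zfy1 stands at 26.6 CPM in WT and 332 CPM in KO.

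Across all genes, early prophase-like cells were compared next, as sums of 483129 UMIs from 90 WT cells and 2455840 UMIs from 522 KO cells. Beyond the sex-linked genes, several autosomal genes stood higher in KO, while the meiotic cohesin subunits Smc1b and Stag3 were at similar levels in both libraries. The piRNA list stood lower in KO than matched random lists. The median log2 ratio of all genes was 0.21, so smaller ratios are no more than the overall shift. The first 12 genes higher in KO by the fixed rule were Cfap47, Zfy2, Vdac1, Nxt2, Cpe, Aard, Ccng1, Kalrn, Furin, Gsta4, Zfy1 and Cst12. Of these, Cpe, Aard, Gsta4 and Cst12 stood at 18.7% to 23.1% of their whole-library level in KO, the range of free RNA. Ratios are printed as counted, also where WT had 1 to 3 UMIs; ranks used counts of at least 3. Cfap47, X-linked, had 1 UMI in WT and stood at 73.3 CPM in KO (log2 5.15, 2.65 to 10.46). Vdac1 was at 4.14 CPM in WT and 82.7 CPM in KO (log2 4.32, 2.45 to 7.38), but in KO that was 38.05% of its whole-library level, so part of it can be free RNA. Ccng1 was at 2.07 and 46.4 CPM (4.49, 1.98 to 9.80). Furin was at 6.21 and 46.0 CPM (2.89, 1.31 to 5.19). Kalrn was at 26.9 and 186 CPM (2.79), but its ratio was −0.0561 in Stra8-led cells. With low counts set to 3, Ccng1 and Furin were each at 0.62 in Stra8-led cells, with counting intervals that included 0, and Vdac1 at 1.66. Cfap47 had 0 UMIs in both libraries there. In Rad51ap2-led cells, which were not matched by stage, Ccng1 was at 2.97, Furin at 3.00, Vdac1 at 3.72 and Cfap47 at 3.97.

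The first 12 genes lower in KO were Prm2, Prm1, Tnp1, Tnp2, Smcp, Gsg1, Gapdhs, Odf1, Oaz3, Akap4, Irgc1 and Rbakdn. Prm1 stood at 3467 CPM in WT early prophase-like cells and 3977 CPM in WT somatic-like cells, and Prm2 at 3316 and 3602 CPM, so these are the level of free RNA. Among cohesin subunits, Smc1b was at 1310.2 CPM in WT and 1433 CPM in KO, Stag3 at 393 and 441 CPM, and Rec8 at 22.8 and 31.4 CPM. Their log2 ratios of 0.13, 0.16 and 0.46 did not pass the overall shift beyond counting error, and that of Smc1b turned to −0.0855 when the median gene was set to no difference. Rec8 in WT was not above its 30.2 CPM in WT somatic-like cells (16.5 to 50.7), so likeness between the libraries is not shown for Rec8. Rad21 was at 35.2 CPM in WT and 66.4 CPM in KO (log2 0.92, 0.19 to 1.73), and the X-linked subunits Smc1a and Stag2 at 37.3 and 39.3 CPM in WT and 105.9 and 106 CPM in KO. Rad21 in KO stood at 32.9% of its whole-library level, which leaves room for free RNA. Its ratio was −1.68 with the top 5% of doublet scores left out. That setting put 250 WT cells in this class and left 1 WT cell spermatogonia-like. WT spermatogonia-like cells had a higher Rad21 level, so the −1.68 compares classes of other make-up and does not show a reversal within early prophase-like cells.

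Of the fixed gene lists in early prophase-like cells, the Y-linked genes had a median log2 ratio of 1.72 (1.31 to 2.08, 8 of 8 higher in KO, percentile 100). Cohesin subunits and regulators had 0.41 (0.21 to 0.53, 19 of 22 higher, percentile 99.2), above the range of matched random lists (−0.10 to 0.35). Its X-linked members Smc1a, Stag2 and Hdac8 had log2 ratios of 1.51, 1.43 and 1.047. Without them, an alternative chosen after the data were seen, the median was 0.27 (0.15 to 0.42, percentile 89.3), inside the random range (−0.12 to 0.35). The list of p53 targets and apoptosis had 0.65 (0.24 to 0.99, 14 of 17 higher, percentile 95.9). The p53 median lay inside the range of matched random lists (−0.13 to 0.70) and was 0.22 with 10% of free RNA taken off both libraries, where the autosomal median was 0.0721. The piRNA pathway had −0.35 (14 of 19 lower, percentile 0.0600), led by Tdrd6, Piwil1 and Gtsf1, against a range of −0.13 to 0.33 for matched random lists. Piwil1 stood at 269 CPM in WT and 19.95 CPM in KO, against 51.8 CPM in WT somatic-like cells. Piwil1 is also one of the fixed pachytene markers, and the cells compared were not matched by stage. Tdrd6, at 116 CPM in WT and 4.48 CPM in KO, was at 99.2 CPM in WT somatic-like cells, the level of free RNA, and Gtsf1, at 263 and 83.9 CPM, was at 134 CPM there. Lists near the overall shift were synaptonemal complex and axis (0.09), double-strand break formation and recombination (0.15), DNA damage response and sex chromosome silencing factors (0.17), meiotic entry (0.14), DNA replication (0.11) and unfolded protein response (0.27). Spermatogonial stem cell maintenance had 0.14 over 4 genes, with an interval that includes 0 (−0.70 to 0.77), and −0.92 with 10% of free RNA taken off, so no direction can be given. Meiotic division and cell cycle had −0.08. The lists made largely of transcripts of other cell types were spermiogenesis (−7.81), steroidogenesis (1.53), Sertoli cell function (1.41), phagocytosis by Sertoli cells (0.90), dissociation stress and immediate early genes (2.05) and inflammation and interferon response (1.43, 3 genes). With 10% of free RNA taken off, Sertoli cell function and phagocytosis each fell to 0.19, steroidogenesis to −1.83 and the stress list to −2.35. A gene left with under 3 counts in both libraries then has only the ratio of the summed UMIs, 483129 in WT over 2455840 in KO. The stress value is that ratio in log2, so the negative values were not read as a direction. Such genes can also lower the p53, Sertoli and phagocytosis medians of that setting, and how many there were is not given. Those falls therefore do not measure free RNA alone.

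The last comparison was of spermatogonia-like cells, from 1107147 UMIs of 168 WT cells and 5513683 UMIs of 950 KO cells. The X-linked difference was smaller than in early prophase-like cells. The stem cell gene Ret and the meiotic entry gene Stra8 stood higher in KO. They are single members of their lists, whose medians lay inside the ranges of matched random lists. Zfy1 and Zfy2 did not differ beyond counting error. The median log2 ratio of all genes was 0.13. The first 12 genes higher in KO were Wfdc10, Inha, Cpe, Defb36, Impg2, Gstm7, Rhox8, Pex10, Clu, Sgk1, Gpsm3 and Gcnt2. Wfdc10, Inha, Cpe, Defb36, Gstm7, Rhox8 and Clu stood at 14.8% to 18.7% of their whole-library level in KO, the range of free RNA. Above that range, Impg2 had 2.71 CPM in WT and 13.1 CPM in KO (log2 2.27, 0.66 to 4.58) and Pex10 had 2.71 and 13.4 CPM (2.31, 0.71 to 4.62), each from 3 UMIs in WT. The first 12 lower in KO were Prm1, Prm2, Tnp2, Smcp, Gapdhs, Gsg1, Ldhc, Fhl4, Crisp2, Odf1, Tnp1 and Irgc1, spermatid or late spermatocyte genes at the level of free RNA in WT. Prm1 stood at 3560.5 CPM in WT spermatogonia-like cells and Ldhc at 918 CPM, against 3977 and 996 CPM in WT somatic-like cells.

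Stra8 was at 298 CPM in WT and 501 CPM in KO spermatogonia-like cells (log2 0.75, 0.58 to 0.92), Ret at 10.8 and 28.1 CPM (1.37, 0.53 to 2.36) and Etv5 at 9.03 and 18.7 CPM (0.11 to 2.15 for the log2 ratio). Etv5 stood at 125 CPM in WT somatic-like cells and in KO at 41.4% of its whole-library level, so free RNA leaves its direction open. After clustering again, 180 KO cells fell in a sub-cluster led by Zbtb16 and Sall4. Each library was clustered again on its own, so no WT cell could fall in it. Whether the mix of stages within the class differed was not tested. Smc1b was at 656 and 709 CPM and Rad21 at 282 and 328 CPM. Syce1 was at 221 and 123 CPM, Stag3 at 186 and 149 CPM and Rec8 at 37.0 and 24.1 CPM. WT somatic-like cells had 92.7 CPM of Syce1 and 58.2 CPM of Stag3, so free RNA leaves the direction of both open. Rec8 was there at 30.2 CPM (16.5 to 50.7, 14 UMIs), 140% of its whole-library level, which is above the range of free RNA. The cause was not tested, and the direction of Rec8 is left open. Zfy1 was at 12.6 CPM in WT and 11.4 CPM in KO, and Zfy2 at 4.52 and 9.79 CPM. X-linked genes took 2.14% of UMIs in WT and 2.49% in KO. Their median log2 ratio exceeded that of autosomal genes by 0.19 (0.15 to 0.24; 505 genes), was 0.0325 with 10% of free RNA taken off and was −0.16 with 20% taken off, so no direction can be given.

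Of the fixed lists in spermatogonia-like cells, spermatogonial stem cell maintenance had a median of 0.45 (0.26 to 0.75, 11 of 12 higher in KO, percentile 97.2), inside the range of matched random lists (−0.25 to 0.47), and 0.23 with members from 5 UMIs. The list of p53 targets and apoptosis had 0.41 (0.12 to 0.54, 14 of 19 higher, percentile 99.0), with Phlda3 at 10.8 CPM in WT and 22.5 CPM in KO. DNA damage response and sex chromosome silencing factors had 0.22 (13 of 15 higher, percentile 86.6), with Hus1 at 16.3 and 32.6 CPM. The piRNA pathway had −0.12 (−0.23 to 0.03, 13 of 21 lower, percentile 0.710), an interval that includes 0. Of its leading members, Tdrd6 and Gtsf1 stood at 97.5 and 160 CPM in WT, near the 99.2 and 134 CPM of WT somatic-like cells. Piwil1 was at 77.7 CPM in WT and 9.43 CPM in KO (log2 −3.04, −3.57 to −2.53), against 51.8 CPM in WT somatic-like cells, with overlapping intervals. Mael was at 277 CPM in WT and 191 CPM in KO (−0.54, −0.72 to −0.35), against 162 CPM in WT somatic-like cells (127 to 203). That background is larger than the gap between the libraries, so free RNA leaves the direction of Mael open. Lists near the overall shift were cohesin subunits and regulators (0.11), synaptonemal complex and axis (−0.05), double-strand break formation and recombination (0.02), meiotic entry (0.04), meiotic division and cell cycle (0.08), DNA replication (0.12), Y-linked genes (0.16) and unfolded protein response (0.24). The lists made largely of transcripts of other cell types were spermiogenesis (−7.76), steroidogenesis (2.02), Sertoli cell function (1.79), phagocytosis by Sertoli cells (0.73), dissociation stress and immediate early genes (1.95) and inflammation and interferon response (0.65). With 10% of free RNA taken off, Sertoli cell function fell to 0.11, phagocytosis to 0.23 and inflammation to 0.0736. Steroidogenesis was then −2.04 and the stress list −2.32. As in early prophase-like cells, the stress value is the log2 ratio of the summed UMIs (1107147 in WT over 5513683 in KO), left by genes at the floor. The negative values were not read as a direction. Genes at the floor can also lower the Sertoli, phagocytosis and inflammation medians of that setting.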

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

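Of the tests below, those on somatic-like cells per spermatogonium-like cell, on cell recovery and on haemoglobin without the top barcodes were chosen after the result was seen, as were the 20% setting and the nearest-cell comparison as alternatives.

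X-linked genes stood above autosomal genes in KO early prophase-like cells, by a median log2 difference of 0.91. With 20% of each library's profile taken off, the lower end of the interval was 0.59. This argues against spermatid RNA of that amount in the WT library as the whole cause. Elongating spermatid markers stood at 19.5% of their whole-library level in WT early prophase-like cells, though Odf1 alone stood at 66.0%. The whole library only stands in for the free RNA, and larger amounts were not tested. Multicopy families are argued against, since 0.92 remained without them. The stage of the WT cells compared cannot be told apart from genotype. The nearest WT germ cells on autosomal genes gave a lower end of 2.72, but 62.0% of the matches were pachytene-like and pachytene markers were lower in the KO cells by a median log2 of −3.34, so the match failed on stage. A candidate explanation is that sex chromosome silencing is incomplete in KO cells of this stage, and another is that KO cells stop before the stage at which WT cells begin it; neither was tested apart.

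Somatic-like cells were 1.17% of WT and 49.5% of KO cells. Missing later germ cells as the sole cause is argued against for Leydig-like cells, which per spermatogonium-like cell were 18.4 times as many in KO (9.83 to 60.8), and 15.1 to 21.9 times over the 19 combinations of setting and germ cell denominator that gave a ratio. With each library clustered on its own, WT had 0 Leydig-like cells and no ratio was computed. Per spermatogonium-like cell, the loose filter, resolution 0.5 and the top doublet scores left out gave none either, as WT had 0 or 1 such cells. For Sertoli-like cells the ratio was 5.41 (3.84 to 8.04), but 1.28 (1.04 to 1.57) under the strict filter and 0.329 without sex-linked genes in clustering, so for them missing germ cells stay open. With 1 library per genotype, the recovery of somatic cells in each preparation cannot be told apart from genotype. A biological difference in the number of somatic cells also stays open, as untested.

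A KO cluster of 974 barcodes had a median of 1013.5 UMIs and was led by haemoglobin and Sertoli genes. Empty droplets with free RNA and Sertoli-like cells cannot be told apart here. The ratio of Sertoli to Leydig marker UMIs was 4.68 times that of the whole KO library (4.53 to 4.83), past the bound set beforehand. That bound was wrong in 2 ways: the whole library is not the free RNA, and Sertoli genes were what singled the cluster out. Against KO spermatogonia-like cells, whose Sertoli and Leydig markers were read as free RNA, the ratio was 1.99 times as high (1.93 to 2.05). Sertoli markers took 3.35% of UMIs both here and in KO Sertoli-like cells, while the median mitochondrial share was 4.65% here and 2.63% there, so damaged or shallow Sertoli-like cells stay open too. Mean haemoglobin per barcode was 13.9 times that of KO Leydig-like cells (10.2 to 19.3), but haemoglobin also singled the cluster out, and 754 of the 798 haemoglobin UMIs came from 1 barcode. Without the 5 barcodes with most haemoglobin in each set, the ratio was 0.747 (0.461 to 1.21), consistent with free RNA.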

How the results depend on the processing

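Alternatives were fixed before the data were examined except 11, chosen after seeing the data, which are named as added below. No paired analysis was possible because each genotype had 1 library.

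Of 154 shares recomputed, 104 stayed within counting error and 50 moved. In each alternative the KO library had the larger shares of spermatogonia-like, early prophase-like and Sertoli-like cells and the smaller share of pachytene-like and later cells. With at least 200 genes and no mitochondrial limit, WT spermatogonia-like cells were 0% and early prophase-like cells 4.80%, and KO values were 13.6% and 7.46%, with 21.01% before pachytene and 34.9% Sertoli-like. With at least 1000 genes and at most 10% mitochondrial UMIs, WT had 4.94%, 0.312%, 76.8% pachytene-like and later and 5.35% Sertoli-like; KO had 21.1%, 11.5%, 32.6% before pachytene and 29.2% Sertoli-like. At resolution 0.5 WT had 0.0185% spermatogonia-like, 4.02% early prophase-like, 94.7% later and 4.04% before pachytene; at resolution 2 it had 79.4% later. With KO cells projected onto WT clusters, KO had 17.6%, 7.02% and 1.34% pachytene-like and later. With each library clustered on its own, WT had 0% spermatogonia-like, 4.07% early prophase-like, 67.9% later, 4.07% before pachytene and 0% Sertoli-like, and KO had 20.4% Sertoli-like. Without sex-linked genes in clustering, WT had 80.0% later and 11.5% Sertoli-like cells. Of the added settings, naming low-UMI clusters gave 33.7% Sertoli-like KO cells, and leaving out the top 5% of doublet scores gave 0.0195% and 4.87% in WT. Where the WT spermatogonia-like share was near 0, the early prophase-like share (4.02% to 4.87%) came near the 4.78% that both classes hold together as reported. The cause was not tested.

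Of 10 Rad21l values, 8 stayed within counting error. WT spermatogonia-like cells had 35.7 CPM under the strict filter and WT early prophase-like cells 37.0 CPM under the loose one. The Rad21l level of WT spermatogonia-like cells under the loose filter and of WT early prophase-like cells under the strict one was not run, for want of 50 cells. Elongating spermatid markers in WT somatic-like cells took 2.82% of UMIs under the strict filter; the cause was not tested.

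The X-linked difference in early prophase-like cells stayed above 0 in each setting. It was 1.08 at 50 UMIs, 0.80 at 5 UMIs, 0.80 with 10% of free RNA taken off and 0.97 without sex-linked genes in clustering; added settings gave 0.65 with 20% taken off, 1.15 with low counts as counted, 0.35 in Stra8-led cells, 1.57 in Rad51ap2-led cells and 2.84 against the nearest WT cells. In spermatogonia-like cells it was 0.0325 with 10% and −0.16 with 20% taken off. The profiles taken off held 0.906% X-linked UMIs in WT and 3.56% in KO, against 2.14% and 2.49% in the spermatogonia-like cells, so taking them off raises the X-linked share in WT and lowers it in KO by construction.

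Of 230 list medians, 196 stayed within counting error, 29 moved and 5 turned. After taking off 10%, genes under the floor of 3 in both libraries have only the ratio of the summed UMIs. The negative medians of steroidogenesis and stress given for that setting therefore show no direction. Other medians of that setting can be lowered by such genes too. In spermatogonia-like cells, 50 UMIs gave −8.07 for spermiogenesis and 2.16 for Sertoli function; 5 UMIs gave 0.23 for stem cell maintenance and 0.00576 for inflammation. Taking off 10% gave −6.91 for spermiogenesis, −2.04 for steroidogenesis, 0.11 for Sertoli function, 0.23 for phagocytosis, −2.32 for stress, 0.0736 for inflammation and 0.0109 for the unfolded protein response. Projection gave 0.17 for the synaptonemal complex, and the per-cell mean 2.18 for stress. Low counts as counted (added) gave −9.20 for spermiogenesis, 3.72 for steroidogenesis and 1.45 for inflammation. In early prophase-like cells, 50 UMIs gave −7.96 for spermiogenesis, 2.02 for steroidogenesis, 2.28 for Sertoli function and 2.53 for stress; 5 UMIs gave −6.93 for spermiogenesis and −0.26 for inflammation. Taking off 10% gave 0.22 for p53, −0.92 for stem cell maintenance, −1.83 for steroidogenesis, 0.19 for Sertoli function, 0.19 for phagocytosis and −2.35 for stress. Projection gave 1.81 for Sertoli function. Low counts as counted (added) gave −8.69 for spermiogenesis, 4.14 for steroidogenesis, 2.36 for Sertoli function and 2.83 for stress. Without X-linked members (added), Sertoli function was 1.77. The cause was not tested.

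Of 1457 gene ratios, 1257 stayed within counting error, 186 moved and 14 turned. Rnf212 in spermatogonia-like cells was −0.32 with cells thinned to 2000 UMIs. In early prophase-like cells, Smc1b was −0.0855 with the median gene set to no difference. In Stra8-led cells (added) Kalrn was −0.0561, Smc1b −0.10, Syce2 −0.36, Mlh3 0.11, Id4 0.0371, Ccnb3 −0.34 and Mcm7 0.16; in Rad51ap2-led cells (added) Smc1b was −0.32. With the top 5% of doublet scores left out (added), which put 250 WT cells in this class and left 1 spermatogonia-like, Rad21 was −1.68, Exo1 −0.00221, Foxo1 −0.76 and Abca1 −0.43. With 20% of free RNA taken off, 9 of 24 named genes in spermatogonia-like and 13 of 24 in early prophase-like cells were shared with the planned list.

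Equal weight to each cluster, and each cluster by itself, were not run, since 0 clusters had 50 cells in both libraries. Spermatogonia-like gene ratios without the top doublet scores were not run either, as 1 WT cell was left in that class. Depth limits genes with few WT UMIs most, since WT early prophase-like cells held 483129 UMIs in all.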

Other observations

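The values below belong to no comparison, and no test was run on them. KO Leydig-like cells had Cyp17a1 at 6214 CPM, Insl3 at 3487 CPM, Star at 3036 CPM and Hsd3b1 at 1348 CPM, and also Fos at 2365 CPM and Egr1 at 1692 CPM. KO Sertoli-like cells had Clu at 8805 CPM, Inha at 1255 CPM and Sox9 at 652 CPM, with Egr1 at 507 CPM and Fos at 464 CPM. With 7 Leydig-like and 37 Sertoli-like cells in WT, these levels were not compared between libraries.

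A KO cluster of 76 Sertoli-like cells was led by Wfdc18, Hrk and Gadd45a and held 0 WT cells. The WT pachytene and diplotene-like class joined a cluster of 409 cells led by Piwil1, with a median of 30683 UMIs, and one of 523 cells with a median of 1853 UMIs and 0 markers among its 10 leading genes, so the name of the latter rests on its marker score alone.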
